A study of Drosophila melanogaster with 8 samples.

How the data were processed

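Total RNA from whole heads of 6-day-old, socially naive adult Drosophila melanogaster was sequenced by the authors. About 90 heads went into each sample. Flies of the Canton-S line (CantonS below) and of a hyper-aggressive line derived from it (Bully) had been raised at 19C or at 25C, which gave 4 groups with 2 libraries each, described by the series as independent biological replicates. The 8 library columns of the deposited table carry the group names but no replicate number, so the libraries of a group are called a and b in column order, as names only, and the replicates were not paired.

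The deposited values are RPKM per gene (reads per kilobase of gene, scaled to library size), made by the authors. Per the submitters' processing notes, reads were aligned with TopHat2 2.0.4, edgeR 3.8.6 was used. The genome builds named are dm3 and BDGP5. Read counts were not used here. Whether the library sizes behind the RPKM were rescaled is not stated in the sources used here. The steps between RPKM values gave the relative sizes of the libraries. After scaling by these, a multiplier was searched for each gene. It turned the values of 9365 of the 13921 genes with values in at least 2 libraries (67.3%) into whole reads within 0.001 of a read. Whole reads were found for 98.4% of genes with a single annotated transcript and for 3.0% of genes with 5 or more. Genes with values in few libraries can meet this tolerance by chance. The effective library size came from the steps and lengths of genes with a single annotated transcript, where 2294 of the 4164 checked gave the modal size. The effective library sizes lay between 47.6 and 117.8 M reads (M, mega), of which 37.0% to 41.1% fell in genes. A single read in a gene of 1 kb was worth 0.00849 to 0.02103 RPKM, and 3 reads, the most that a count of 0 allows, were worth 0.0255 to 0.0631 RPKM. These limits cover counting error only, since reads are not independent molecules.

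Genes with a mean of at least 1 RPKM over the 8 libraries were tested (8480 genes), on the scale of log2(RPKM + 0.5). One linear model with the 4 group means was fitted to all 8 libraries with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, and eBayes with a mean-variance trend). Residual degrees of freedom were 4 and the variance prior added 4.5. There were 7 comparisons: Bully against CantonS at 25C, at 19C and averaged over temperatures; 25C against 19C in CantonS, in Bully and averaged over lines; and the line by temperature interaction. Tests were two-sided, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. A gene that passed is said to have risen or fallen, or to be higher or lower. The pseudocount shrinks the log2 differences of genes with low values.

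There were 41 gene lists, covering pathways and cell type markers. Of their 692 symbols, 683 were matched in the table, with older symbols looked up through the reference annotation. The 32 lists with at least 3 tested members were tested against all other genes with limma's camera, at a preset correlation between genes of 0.01, adjusted over the lists within a comparison. Camera was repeated with the correlation estimated from the data. For each list the members that passed were counted over all genes tested and also adjusted over the list alone.

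Named genes were chosen by a fixed rule. It took the 10 genes with the largest rise and the 10 with the largest fall among those that passed and whose libraries did not overlap between the groups, or the 5 smallest p as values where fewer than 5 passed. It added up to 4 members of each described list by the size of the test statistic. It also took CG13646, a gene that the study chose on these samples, so that its difference is not independent evidence. CG13646 lies below the filter on low values, and it was tested in the same model fitted without the filter. Lists, comparisons, the naming rule and the alternatives were fixed before the data were examined, except where the text says otherwise.

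The model was tested on simulated data built from the table's own spread: of the genes given a 2-fold change, 88.9% were called in the line comparison at 25C, 87.9% at 19C, 52.0% in the interaction, 88.8% for temperature in CantonS and 91.9% for temperature in Bully. Of the 8372 to 8390 genes in each simulated comparison, 4 to 15 that had been left unchanged were called. Camera called 0 of 30 random gene sets in each comparison. The simulated genes varied independently of each other, with the same spread in all 4 groups. The simulation therefore gives no error rate for groups of unequal spread or for genes that vary together.

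The alternatives were other pseudocounts, no filter and a stricter filter on low values, median-of-ratios rescaling and quantile normalization, a fit of only the groups compared, a fit without the variance trend or with a robust prior, an adjusted p below 0.1, a 2-fold minimum, limma's fry for the lists, and leaving out each library in turn. Removing each library's trend with gene length and weighting the libraries were added after seeing the data. Gene lengths and the order of genes came from a Release 6 annotation, a later build than the authors' dm3, so no coordinates are given; lengths were found for 8411 tested genes (99.2%). Neighbouring genes and permutations were computed with Python 3.11.15, NumPy 2.4.6 and SciPy 1.17.1. No column of the table was left out. Among the tested genes, 99 had the same values as another gene. In 91 pairs of overlapping tested genes (39 of them with identical values) the ratio of the values varied by a factor of at most 1.05 over the libraries, and the pairs were counted as separate genes.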

Results

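Gene expression was measured by RNA sequencing in whole heads of 6-day-old adult flies from 2 lines, Canton-S (CantonS) and the hyper-aggressive Bully line, each raised at 19C or 25C. Each of the 4 groups had 2 libraries, so every group mean below has n = 2. Effective library sizes were 114.8 and 79.9 M reads (M, mega) for Bully 19C, 99.2 and 84.3 for Bully 25C, 107.6 and 117.8 for CantonS 19C, and 47.6 and 90.0 for CantonS 25C. Values are RPKM. The 8480 genes with a mean of at least 1 RPKM were tested with limma on log2(RPKM + 0.5). Across genes, which are not independent replicates, the log2 values of replicates correlated at 0.9927 in Bully 19C, 0.9840 in Bully 25C, 0.9765 in CantonS 19C and 0.9831 in CantonS 25C. The highest value of any listed testis gene was 1.94 RPKM (Mst87F) and of any accessory gland gene 9.10 RPKM (Acp95EF, at 3.15 RPKM or more in every library). It was 0.45 RPKM (Cp7Fa) for ovary follicle genes and 2.03 RPKM (Mal-A1) for midgut genes. Ser7, in the list of gut serine proteases, was at 19.65 to 27.81 RPKM, and it was not called between the lines (adjusted p = 0.512 at 25C and 0.655 at 19C). Acp95EF was lower in Bully at 19C (-0.93, SE 0.21, adjusted p = 0.0258) and averaged over temperatures (-0.60, SE 0.15, adjusted p = 0.0372). Both calls of Acp95EF were lost without any 1 of the Bully libraries or CantonS 19C b (adjusted p up to 0.168 and 0.139), without the filter (adjusted p up to 0.0788) and with each library's length trend removed (0.216 and 0.135). That at 19C was also lost in a fit of only the groups compared (0.0643), and that of the average without CantonS 25C a (0.101). The male-specific RNA roX1 lay between 120.68 and 159.48 RPKM in every library.

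The line comparison at 25C asked which head transcripts differ between Bully and CantonS flies raised at the warmer temperature. The largest difference was in Cyp6a2, a cytochrome P450 linked to insecticide detoxification, at 64.1 ± 0.75 RPKM (SD) in CantonS and 0.36 ± 0.05 RPKM in Bully (log2 difference -6.22, SE 0.13, adjusted p = 1.26e-07). The P450 gene Cyp6a17 (-3.70, SE 0.22, adjusted p = 7.43e-05) and the glutathione transferase GstE8 (-3.08, SE 0.25, adjusted p = 4.75e-04) were lower in Bully too. So were the DNA photolyase phr (-2.95, SE 0.15, adjusted p = 3.68e-05) and the glycolytic gene Gapdh2 (-2.41, SE 0.22, adjusted p = 9.32e-04). Obp99b, an odorant binding protein, was higher in Bully, at 126 ± 28.6 RPKM against 10.6 ± 0.44 RPKM (log2 difference 3.50, SE 0.17, adjusted p = 3.68e-05). The storage protein gene Lsp1beta (3.03, SE 0.11, adjusted p = 7.09e-06) and the ABC transporter gene Mdr50 (2.59, SE 0.16, adjusted p = 9.21e-05) rose as well. The G protein-coupled receptor gene mthl14 (3.02, SE 0.18, adjusted p = 9.21e-05) and CG7366 (3.28, SE 0.15, adjusted p = 3.25e-05) also rose. The other genes with the largest rises were CG31205, CG34423, CR44168, CG33926 and Cyp4d1, by 2.21 to 2.58 on the log2 scale. Those with the largest falls were CG34215, Cyp4p2, CG7768, CG3397 and the defensin gene Def, with log2 differences from -2.92 to -2.27.

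Of the 8480 genes tested at 25C, 158 were higher and 99 lower in Bully, 257 in all. Of these, 139 differed at least 2-fold. Among 59 cytochrome P450 genes 9 rose and 6 fell, with 18 and 7 adjusted over the list alone. Among 48 immune genes 3 rose, among them IM18 (2.01, adjusted p = 0.0145) and Drsl5 (1.37, adjusted p = 0.0295). IM18 overlaps CG10332 and has identical values in every library, so the reads of these genes cannot be separated. Of the immune genes 2 fell, IM23 (-2.02, adjusted p = 0.00162) and Def (-2.27, adjusted p = 0.0035), and the counts were 10 and 4 adjusted over the list alone. Of 39 phototransduction genes 3 rose and 1 fell, with 8 and 1 adjusted over the list alone. There were rises in the rhodopsins Rh6 (1.13, SE 0.16, adjusted p = 0.00822) and Rh4 (0.98, adjusted p = 0.045) and a fall in Rh5 (-0.78, adjusted p = 0.0368). Camera put this list up (adjusted p = 0.0306, against adjusted p = 0.998 with an estimated correlation). Of 23 eye pigment genes 2 rose, cd (1.22, adjusted p = 0.0155) and se (1.06, adjusted p = 0.0235), with 5 adjusted over the list alone. Camera put this list up as well (adjusted p = 0.0353, against adjusted p = 0.998 with an estimated correlation). The 2 other lists it put up were 14 photoreceptor markers (2 rose and 1 fell, 4 and 1 adjusted over the list alone) and 3 female-enriched head transcripts (1 rose and 0 fell, 2 adjusted over the list alone). Both were at adjusted p = 0.0306, and at adjusted p = 0.998 with an estimated correlation. So a rise of photoreceptor transcripts as a whole was not told apart from one of phototransduction genes. Of 21 cuticle protein genes 1 rose and 5 fell, with 3 and 5 adjusted over the list alone, among the falls Lcp65Ag1 (-1.61, adjusted p = 0.0073). In the list of 15 aggression genes from earlier fly work and in the list of 30 genes of biogenic amine synthesis, transport and reception, limma called 0 genes, also adjusted over the list alone, with 1 and 4 genes at an unadjusted p below 0.05. The 20 genes with the largest changes passed in every alternative that tested them and with any library left out. Those with a mean below 5 RPKM, such as CG7366 and mthl14, were not tested under the stricter filter. The count of 257 was 77 without Bully 25C a, 100 without Bully 25C b, 108 without CantonS 25C a, 394 without CantonS 19C a and 398 without CantonS 19C b. The phototransduction list did not pass without Bully 25C a (adjusted p = 0.172), without CantonS 25C b (adjusted p = 0.281) or after quantile normalization (adjusted p = 0.228), nor did the eye pigment list (adjusted p = 0.217, 0.199 and 0.0843) or the photoreceptor list (adjusted p = 0.172, 0.0975 and 0.413). The female-enriched list did not pass without Bully 25C a (adjusted p = 0.172) or CantonS 25C b (adjusted p = 0.199). With single libraries of the 25C groups left out IM23 and Def kept their calls, and Lcp65Ag1 (adjusted p up to 0.072), Rh6 (0.0765), IM18 (0.113), cd (0.115), se (0.15) and Drsl5 (0.22) lost theirs, all of them without Bully 25C a. Rh4 (up to 0.212) and Rh5 (up to 0.25) lost theirs without any 1 of the 6 libraries other than those of CantonS 19C.

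**Figure D1:**
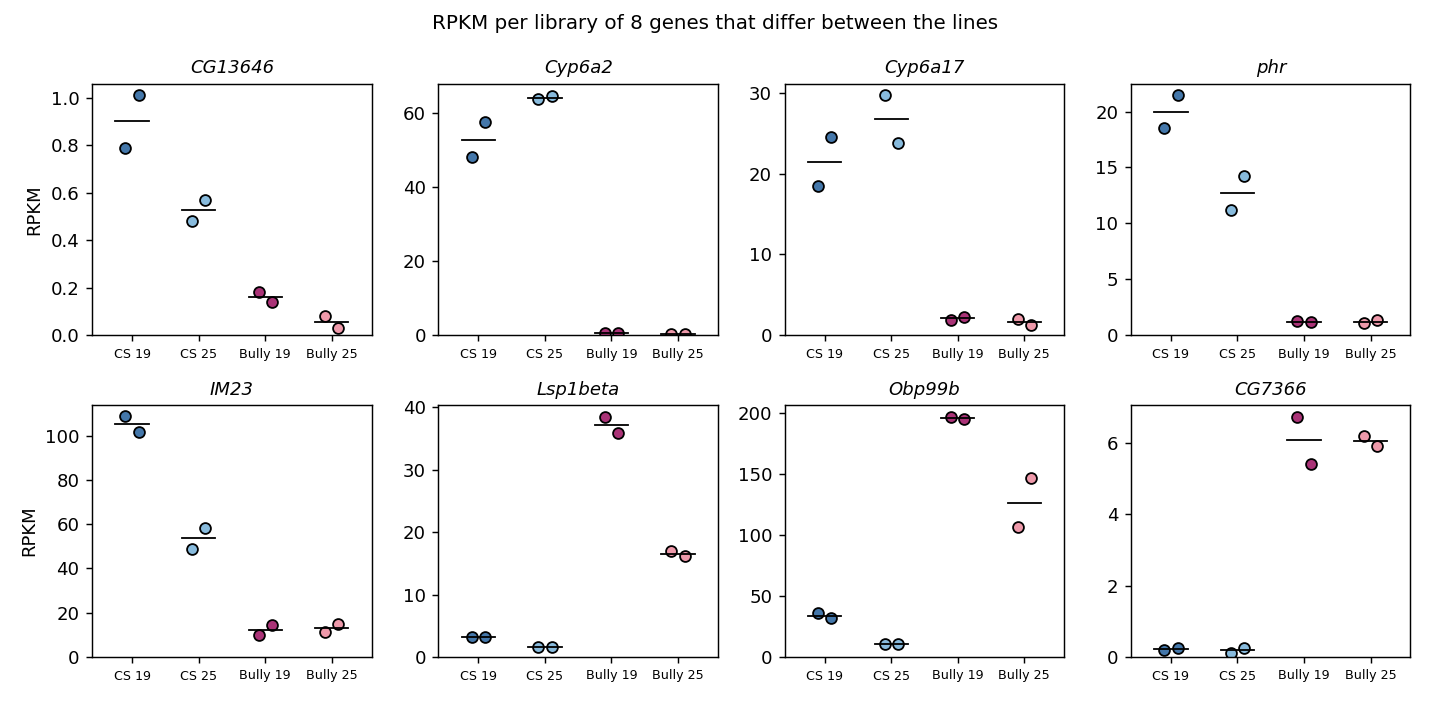
RPKM (linear axis from 0, its own scale for each gene) of 8 genes in each of the 8 libraries, as 1 point per library with a bar at the group mean, for CantonS (CS) and Bully raised at 19C or 25C. CG13646, Cyp6a2, Cyp6a17, phr and IM23 lie lower in all 4 Bully libraries and Lsp1beta, Obp99b and CG7366 lie higher.

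The line comparison at 19C asked the same question of flies raised at the cooler temperature. The phenotype of the Bully line is described as dependent on rearing temperature, and the data used here hold no measure of behaviour. Neither line comparison therefore shows which transcripts go with aggression. Cyp6a2 again had the largest difference, 52.7 ± 6.68 RPKM in CantonS against 0.51 ± 0.07 RPKM in Bully (log2 difference -5.71, SE 0.13, adjusted p = 2.61e-07). The immune-induced gene IM23 fell from 105 ± 5.18 to 12.3 ± 3.17 RPKM (-3.06, SE 0.21, adjusted p = 1.13e-04). The log2 difference of phr was -3.58 (SE 0.15, adjusted p = 9.06e-06). The gene of another receptor of the methuselah-like family, mthl8, fell from 3.54 ± 0.45 RPKM to 0.00 RPKM (-3.01, SE 0.13, adjusted p = 1.34e-05). Lsp1beta rose from 3.22 ± 0.01 to 37.2 ± 1.87 RPKM (3.34, SE 0.11, adjusted p = 3.12e-06), and Cyp6a8 from 8.23 ± 3.13 to 64.1 ± 8.48 RPKM (2.93, SE 0.34, adjusted p = 0.00198). The other largest rises were in CG7366, mthl14, CG31205, Obp99b, Mdr50, CG43402, CG10062 and CG10924, by 2.18 to 3.18 on the log2 scale. The other largest falls were in CG34215, Cyp4p2, CG7768, Cyp6a17, snoRNA:Me18S-C1096 and CG44008, with log2 differences from -3.81 to -2.80. These 20 genes passed in every alternative that tested them and with any library left out, except snoRNA:Me18S-C1096. Its call was lost in 3 other alternatives and without Bully 19C a, Bully 19C b or CantonS 19C a. Genes with a mean below 5 RPKM, such as mthl8, were not tested under the stricter filter.

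At 19C, 292 genes were higher and 684 lower in Bully, 976 in all. Of 82 ribosomal protein genes 0 rose and 36 fell (70 adjusted over the list alone), with a median log2 difference of -0.73. Camera placed this list down (adjusted p = 5.55e-18), and with an estimated correlation it did not pass (adjusted p = 0.558). Among them were RpS27 (-1.24, SE 0.15, adjusted p = 0.00223) and RpL29 (-1.76, SE 0.25, adjusted p = 0.00494). Of 43 neuropeptide and receptor genes 1 rose and 9 fell (1 and 14 adjusted over the list alone; camera adjusted p = 0.00168, down, and adjusted p = 0.558 with an estimated correlation). The falls included the clock neuropeptide Pdf (-1.55, SE 0.16, adjusted p = 0.0012), the insulin-like peptide Ilp2 (-1.30, SE 0.19, adjusted p = 0.00561) and the tachykinin gene Tk (-1.12, SE 0.17, adjusted p = 0.00743). Tk was the single call among the 15 aggression genes, also adjusted over the list alone, and it was lost without Bully 19C b (adjusted p = 0.0743). Of 11 hemocyte markers 4 rose and 0 fell (7 adjusted over the list alone). Camera placed them up (adjusted p = 2.81e-04, and adjusted p = 0.558 with an estimated correlation). The log2 rise was 2.05 in nimC1 (SE 0.24, adjusted p = 0.00208) and 1.48 to 1.82 in Ppn, Hml and proPO-A1. CantonS 19C stood apart here from CantonS 25C as well as from Bully. The mean of nimC1 was 1.94 RPKM in CantonS 19C, 6.02 in CantonS 25C, 9.77 in Bully 19C and 12.21 in Bully 25C. For Hml the means were 1.65, 5.62, 5.60 and 5.34 RPKM. Of the P450 genes 12 rose and 5 fell (14 and 6 adjusted over the list alone), and camera placed them up (adjusted p = 3.58e-04, and adjusted p = 0.63 with an estimated correlation). Of the immune genes 2 rose and 8 fell (2 and 9 adjusted over the list alone), including IM2 (-2.02, adjusted p = 2.19e-04). Camera placed the proteasome list down (adjusted p = 0.00291, and adjusted p = 0.617 with an estimated correlation). With each library's length trend removed this list did not pass (adjusted p = 0.144). The neuronal gene elav was at 1.43 RPKM in CantonS 19C b and at 3.04 to 4.24 RPKM in the other libraries. The split of 292 and 684 was 403 and 516 after median-of-ratios rescaling and 395 and 466 after quantile normalization. The total of 976 was 159 without Bully 19C a, 145 without Bully 19C b, 1996 without CantonS 19C a and 572 without CantonS 19C b. Without Bully 19C b the calls of Ilp2 (adjusted p = 0.0628), Ppn, Hml and proPO-A1 (up to 0.0828, 0.13 and 0.138) were lost as well, the last 3 also without CantonS 19C b. With each library's trend with gene length removed, 589 of the 970 called genes with a known length still passed. All but 1 of the 970 (969) kept their sign. The totals that passed were then 492 higher and 400 lower, 892 in all.

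The lines differed in 166 genes at both temperatures, all with the same sign, 76 higher and 90 lower in Bully. For independent calls 5.4 and 8.0 were expected, but both comparisons used the same estimate of spread for each gene. Of the 976 genes called at 19C, 624 had the same sign at 25C. Of the 257 called at 25C, 239 had the same sign at 19C. Across all tested genes, which are not independent replicates, the line differences at 19C and 25C correlated at r = 0.38 and Spearman's rho = 0.05. Averaged over temperatures, 371 genes were higher and 374 lower in Bully. The leading genes were Cyp6a2 (-5.97, SE 0.09, adjusted p = 9.61e-09), Lsp1beta (3.18, SE 0.08, adjusted p = 2.52e-07), CG7366 (3.23, SE 0.11, adjusted p = 1.21e-06) and phr (-3.26). Of the 59 P450 genes 17 rose and 6 fell (21 and 8 adjusted over the list alone; camera adjusted p = 0.00276, up, and adjusted p = 0.758 with an estimated correlation). Among the 745 calls, 309 (144 higher, 165 lower) passed with any single library left out. Their number was 392 without Bully 19C a, 350 without Bully 19C b, 414 without Bully 25C a, 487 without Bully 25C b and 1171 without CantonS 19C a.

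**Figure D2:**
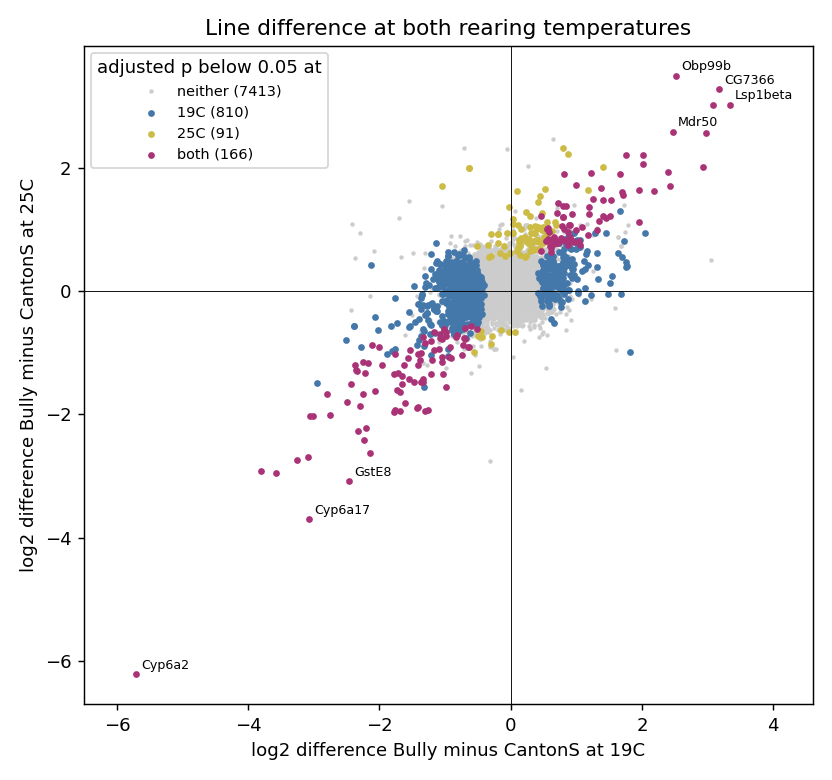
Log2 difference between Bully and CantonS in each of the 8480 tested genes (points) at 19C (horizontal axis) and at 25C (vertical axis), coloured by where the adjusted p was below 0.05. The 166 genes called at both temperatures lie in the quadrants of equal sign, with Cyp6a2 at -5.71 and -6.22.

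CG13646, the gene that the study followed up, was lower in every Bully library. Its level at 25C was 0.06 ± 0.04 RPKM in Bully and 0.52 ± 0.06 RPKM in CantonS, 9.3-fold lower, and at 19C it was 0.16 ± 0.03 against 0.90 ± 0.16 RPKM, 5.5-fold lower. These levels rested on 13 and 4 reads in Bully 25C, 33 and 18 in Bully 19C, 36 and 81 in CantonS 25C, and 134 and 188 in CantonS 19C. Without Bully 25C a the fold at 25C was 17.4, without Bully 25C b it was 6.3, and it was 8.5 to 10.1 without either CantonS 25C library. With single 19C libraries left out the fold at 19C was 4.9 to 6.3. In limma without the filter the log2 difference was -0.88 at 25C (SE 0.10, adjusted p = 0.0154) and -1.07 at 19C (SE 0.10, adjusted p = 0.00617). With a pseudocount of 0.1 these were -2.01 and -1.92. An exact two-sided permutation test of the 4 Bully against the 4 CantonS libraries gave p = 0.0286, the smallest that its 70 splits can give, as follows where every library of 1 line lies lower. The study chose this gene on these samples, so the p is no independent evidence. The difference between the temperatures did not pass (interaction 0.19, SE 0.15, adjusted p = 0.523). The call at 25C was lost without Bully 19C a (adjusted p = 0.0938), Bully 19C b (0.0928), Bully 25C a (0.0791), Bully 25C b (0.125), CantonS 25C a (0.0808) or CantonS 25C b (0.0829). The call at 19C was lost without Bully 19C b (0.0582).

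The interaction asked whether the line difference depends on rearing temperature. By limma 0 single genes passed, with 2018 genes at an unadjusted p below 0.05 and 280 at an adjusted p below 0.1. The genes with the smallest p, all at an adjusted p of 0.0921, were CG44205 (1.32, SE 0.18), CG10418 (1.62, SE 0.23), mRpS6 (1.16, SE 0.17), Mesh1 (1.16, SE 0.17) and CG11597 (2.75, SE 0.42). In each the line difference was more positive at 25C. Camera passed 12 of the 32 lists, the ribosomal protein list first (adjusted p = 5.50e-17), with median line differences of 0.18 at 25C and -0.73 at 19C. With an estimated correlation 0 lists passed, the ribosomal list being at adjusted p = 0.6, and fry passed 0 lists too. In the hemocyte list the medians were -0.00 at 25C and 0.67 at 19C (adjusted p = 3.87e-04, and adjusted p = 0.6 with an estimated correlation). With each library's length trend removed 3 of the 12 lists still passed, the ribosomal list among them (adjusted p = 6.15e-12) and the hemocyte list not (adjusted p = 0.0784). Without CantonS 19C a the count of genes was 903, without CantonS 25C b it was 466 and without Bully 25C b it was 5. The median interaction of all genes was 0.115 as deposited, and rescaling shifted it by -0.138 (median of ratios) or -0.132 (quantile).

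**Figure D3:**
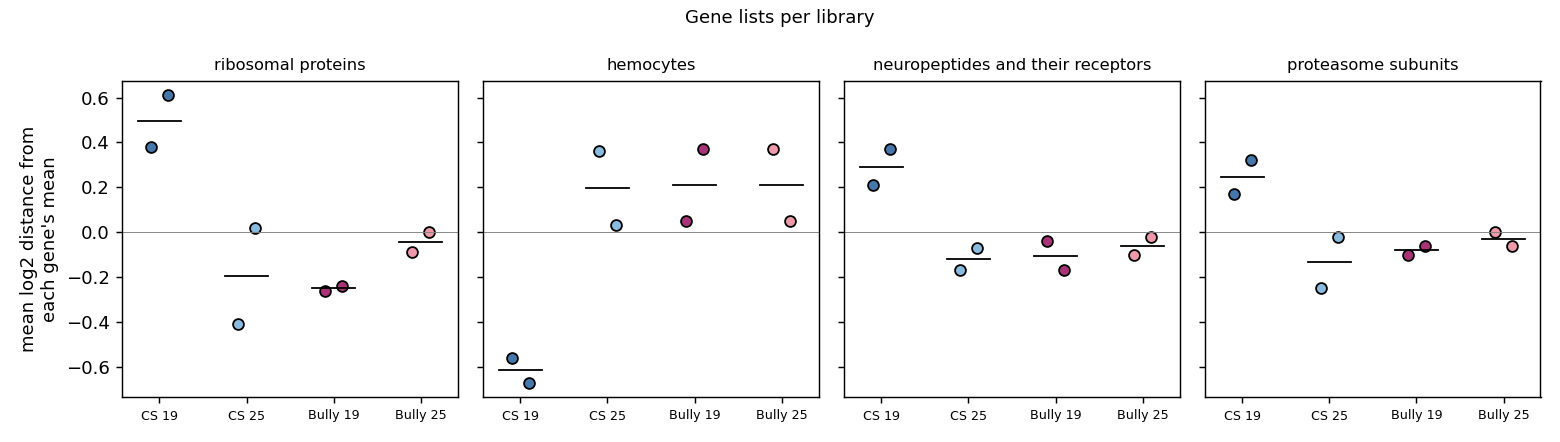
Mean log2 distance of the genes of 4 lists from each gene's own mean over the 8 libraries (vertical axis), as 1 point per library with a bar at the group mean, for CantonS (CS) and Bully raised at 19C or 25C. The ribosomal protein list lies at 0.38 and 0.61 in the CantonS 19C libraries and between -0.41 and 0.02 in the others, and the hemocyte list at -0.56 and -0.67 in CantonS 19C and between 0.03 and 0.37 in the others.

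The temperature comparison in CantonS asked which transcripts follow rearing temperature in control flies. At 25C the insulin-like peptide Ilp3 was at 7.58 ± 1.29 RPKM against 20.2 ± 0.08 RPKM at 19C (-1.36, SE 0.15, adjusted p = 0.0274). Lower levels were also found for Ilp5 (-1.15, adjusted p = 0.0372), Ilp2 (-1.01, adjusted p = 0.0411) and the drosulfakinin gene Dsk (-0.87, adjusted p = 0.0389). The amine-conjugating enzyme gene e rose from 8.15 ± 0.93 to 27.6 ± 1.71 RPKM (1.70, SE 0.28, adjusted p = 0.0375), and the hemocyte gene proPO-A1 from 1.11 ± 0.08 to 10.3 ± 4.94 RPKM (2.68, SE 0.38, adjusted p = 0.034). Other large rises were in CG42392, CG1942, CG3790, CR43469, Hml, Ppn, nimC1 and proPO45, by 1.40 to 1.83. Of these, CG3790 and CR43469 overlap and kept a ratio of 0.888 to 0.890 in every library, as where the same reads are counted for both, so they count as 1 signal. Large falls were in CG10621 (-1.81, SE 0.21, adjusted p = 0.0274), Obp99b (-1.63), Rab5 (-1.43), CG18598 (-1.43), Roc2 (-1.38). The largest falls were in 7SLRNA:CR42652 and 7SLRNA:CR32864 (-2.22 each, identical values), ahead of CG10621. After CG10621 came CG10332 and IM18 at -1.72 each, also with identical values.

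In CantonS 90 genes rose and 454 fell from 19C to 25C, 544 in all, with adjusted p of 0.0274 or more. Of 82 ribosomal protein genes 23 fell and 0 rose (66 adjusted over the list alone). Of 43 neuropeptide and receptor genes 9 fell and 0 rose (17 adjusted over the list alone). Of 48 immune genes 7 fell and 0 rose (15 adjusted over the list alone). Of 11 hemocyte markers 5 rose and 0 fell (5 adjusted over the list alone). Camera gave adjusted p = 3.82e-15, 0.00157, 0.0101 and 1.72e-04 for these lists, and adjusted p = 0.569, 0.569, 0.624 and 0.569 with an estimated correlation. The line comparison at 19C and the interaction use the same CantonS 19C libraries. The ribosomal, neuropeptide and hemocyte results of these comparisons are therefore not separate evidence. Across genes, log2 length correlated at r = 0.55 with the temperature difference in CantonS. It correlated at -0.52 and -0.25 with the differences between replicates (b minus a) of CantonS 19C and CantonS 25C. With each library's length trend removed limma called 0 genes, after median-of-ratios rescaling 0 and after quantile normalization 17 (9 up, 8 down), against 2706 genes at an unadjusted p below 0.05 as deposited. The median difference of all genes was -0.108, and these scalings shifted it by 0.113 and 0.102. The count was 0 without CantonS 19C b, without CantonS 25C a or without either Bully 25C library, 6 without either Bully 19C library, 955 without CantonS 25C b and 2261 without CantonS 19C a. Of the 56 named genes that passed, 0 passed in every alternative.

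In Bully, limma called 2 genes between the rearing temperatures, both lower at 25C. The alpha-glucosidase gene tobi, a target of insulin signalling, fell from 50.7 ± 3.77 to 17.1 ± 3.24 RPKM (-1.55, SE 0.16, adjusted p = 0.0257) and Lsp1beta from 37.2 ± 1.87 to 16.6 ± 0.67 RPKM (-1.14, SE 0.11, adjusted p = 0.0257). Both also had lower levels at 25C in CantonS, tobi at -0.82 (adjusted p = 0.0411) and Lsp1beta at -0.83 (adjusted p = 0.034). Genes next in p that did not pass were Osi2 (1.06, adjusted p = 0.224), CR43242 (0.75, adjusted p = 0.26) and the storage protein gene Lsp2 (-1.47, adjusted p = 0.262). Of 9 fat body markers 1 fell and 0 rose (4 adjusted over the list alone), and of 14 photoreceptor genes 0 passed, with 4 at an unadjusted p below 0.05. Camera placed the first list down and the second up, both at adjusted p = 4.62e-05, and both at adjusted p = 0.493 with an estimated correlation. Of the 9 lists that passed, the ribosomal proteins had the smallest p and were up (median 0.23, adjusted p = 1.82e-07, and adjusted p = 0.845 with an estimated correlation), opposite to CantonS. Among the 82 genes limma called 0, with 1 at an unadjusted p below 0.05. With single libraries left out the list was at adjusted p = 1.37e-10 to 2.00e-04. Unadjusted p lay below 0.05 in 272 genes, fewer than the 424 that chance gives. The variance was pooled with CantonS, whose estimated library weights were lower (0.39 and 0.78, against 2.82 and 1.17 in Bully). A pooled variance too large for Bully makes these tests conservative, so the low number does not show that Bully lacks a response. The count of 2 was 0 without Bully 19C a, Bully 19C b, Bully 25C a, CantonS 25C a or CantonS 25C b, and 4 without Bully 25C b, CantonS 19C a or CantonS 19C b. A fit of the Bully libraries alone gave 3 other genes (1 up, 2 down) and lost both calls (adjusted p = 0.0913 for tobi and 0.0507 for Lsp1beta). The count was 49 without the filter and 8 with library weights, both with tobi and Lsp1beta, and 1 after quantile normalization, which lost tobi (adjusted p = 0.0513). With 1 library left out the adjusted p reached 0.482 for tobi and 0.683 for Lsp1beta, whose calls were both lost without Bully 25C b too.

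Averaged over lines, 1 gene rose and 6 fell from 19C to 25C. The RNA snmRNA:400 rose (1.11, SE 0.12, adjusted p = 0.0205), and tobi (-1.19, SE 0.11, adjusted p = 0.0139), Lsp1beta (-0.99, SE 0.08, adjusted p = 0.00861) and Obp99b (-1.14, SE 0.12, adjusted p = 0.0205) fell. The other falls were in CG10621 (-1.18) and in a pair of U3 snoRNA genes with identical values (-0.78 each), mentioned after their values were seen. Of the 544 genes called in CantonS, 146 (26.8%) had the same sign in Bully. The temperature differences of the lines correlated across genes at r = -0.24 (Spearman's rho = -0.34). The count of 7 was 0 without Bully 19C a or Bully 25C a, 1 without CantonS 19C b, 3 without CantonS 25C b and 312 without CantonS 19C a.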

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

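The tests of the library axis, of a response shared by the lines, of the fat body, of the splits with the line as a term, of unequal spread, of the signs and calls with the length trend removed and the intervals from blocks of genes were chosen only after the result was seen, as was the removal of the length trend among the alternatives; the other tests were planned.

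In 12 gene lists the interaction differed from that of all other genes by camera, and each list lost this call with an estimated correlation. The median interaction of all genes was 0.115. Camera does not test whether the line difference of a list itself differs between 19C and 25C. Fry, which tests the genes of a list without the others, passed 0 of the 32 lists. Median log2 line differences at 25C and 19C were 0.18 and -0.73 for ribosomal proteins (adjusted p = 5.50e-17, and adjusted p = 0.6 with an estimated correlation) and -0.00 and 0.67 for hemocyte markers (adjusted p = 3.87e-04 and 0.6). They were 0.14 and -0.34 for proteasome subunits (adjusted p = 0.00454 and 0.612), 0.05 and 0.28 for glia (adjusted p = 0.00469 and 0.433) and -0.09 and 0.14 for voltage-gated and sensory ion channels (adjusted p = 0.00589 and 0.6). Neuropeptides and their receptors had -0.00 and -0.35 (adjusted p = 0.0075 and 0.6), P450 genes 0.13 and 0.26 (adjusted p = 0.00875 and 0.716), and ecdysone and juvenile hormone signalling 0.01 and 0.22 (adjusted p = 0.00875 and 0.433). Immune genes had 0.25 and -0.27 (adjusted p = 0.0109 and 0.612), clock genes 0.03 and 0.18 (adjusted p = 0.02 and 0.433), fast neurotransmitter and synaptic vesicle genes -0.10 and 0.09 (adjusted p = 0.0265 and 0.716), and histone genes 0.42 and -0.51 (adjusted p = 0.0287 and 0.6). With each library's length trend removed 3 of the 12 still passed, ribosomal proteins (adjusted p = 6.15e-12), P450 genes (adjusted p = 3.39e-05) and glia (adjusted p = 0.026), and the other 9 did not, among them hemocyte markers (0.0784), proteasome subunits (0.186) and clock genes (0.681), with ion channels and fast neurotransmitter genes reversed (0.515 and 0.228).

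More genes changed with temperature in CantonS (544) than in Bully (2), but unequal spread of the groups under one pooled variance stays open as the reason: with library weights (2.82 for Bully 19C, 1.17 for Bully 25C, 0.39 for CantonS 19C and 0.78 for CantonS 25C) the counts were 0 and 8, and in fits of only the groups compared 4 and 3. Counting noise in the shallow CantonS 25C a library stays open. Of the 540 called genes with a known length 3.7% had fewer than 50 estimated reads there. A read in a gene of 1 kb was worth 0.02103 RPKM in that library, and the median length of tested genes was 2123 bp. The filter of 1 RPKM by itself therefore tends to keep genes above 50 reads, and the share does not decide. A shared response that Bully shows at a smaller size needs most of the 544 genes to agree in sign. Of them 26.8% did (36.7% of all genes). With each library's length trend removed 40.2% did (42.3% of all genes, and at most 46.3% with single libraries left out). Log2 length correlated with the temperature difference at 0.55 in CantonS and -0.22 in Bully. Since agreement was low over all genes too, an axis across libraries may have set the signs. A smaller shared response therefore stays open. A bias with gene length between the CantonS libraries stays open. With the trend removed 0 genes were called (smallest adjusted p = 0.0528). The median absolute log2 difference of the 540 with a known length went from 0.73 (median SE 0.15) to 0.44 (median SE 0.13). The corrected differences with the earlier SE also gave 0 calls, against 2077 for the earlier differences with the corrected SE. Median-of-ratios rescaling gave 0 too (smallest adjusted p = 0.0532), so a count of 0 is not special to length. The size of the loss was unlike, since rescaling left that median at 0.66 (median SE 0.14). Genes at an unadjusted p below 0.05 went from 2706 as deposited to 2537 with rescaling and 1876 with the length trend removed. An axis that also separates replicates stays open too, since across genes the difference between the CantonS 25C libraries correlated at r = -0.48 with the temperature difference, and that between the CantonS 19C libraries at -0.34. A biological response of CantonS to rearing temperature was not tested apart from these and stays open as well.

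Genes that differed between the lines lay next to each other in the genome more often than shuffled calls did. Among non-overlapping genes there were 39 neighbouring pairs of the same sign against 17.7 for shuffled calls (ratio 2.21, permutation p = 1e-05, the smallest that 100000 resamples can give), which argues against overlapping genes that share reads as the whole cause. Neighbours that vary together between any libraries stay open: the ratio of the CantonS temperature calls was 1.37 (permutation p = 0.122), but the line ratio exceeded it by 0.84 with a 95% interval from -0.04 to 1.66 over resampled blocks of 50 genes. With overlapping genes included it exceeded it by 0.98 (0.23 to 1.77), but those pairs may share reads, and the temperature calls too lay above shuffled calls there (51 pairs against 25.0, ratio 2.04, permutation p = 1e-05, and for line calls 98 against 32.4, ratio 3.02). Haplotype blocks stay open as well, since pairs of called genes 20 to 100 kb apart had a ratio of 1.12 (permutation p = 0.112) with a 95% interval from 0.90 to 1.37, which reaches above the 1.2 set for that explanation, while shorter inherited segments and shared control of gene clusters were not tested.

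The fat body transcripts Lsp1beta, Lsp2 and Obp99b were higher in Bully, by 3.18 (SE 0.08), 1.54 (SE 0.16) and 3.01 (SE 0.12) averaged over temperatures. Camera placed the fixed list of 9 measured fat body genes, which holds Lsp1beta and Lsp2 but not Obp99b, up in that average (adjusted p = 0.00276; 0.661 with an estimated correlation; 4.34e-04 to 0.0264 with single libraries left out) and at 19C (adjusted p = 0.00349; 0.47), and not at 25C (adjusted p = 0.0721; 0.998), with 3 genes risen and 0 fallen in each. A larger amount of fat body in the Bully heads as the whole reason for the 3 rises is argued against, since the other 7 genes of that list had a median log2 difference of 0.09 (SE 0.13), below 0.77, which is 0.5 times the smallest of these rises and the least set for that explanation. Among these 7, Yp3 rose (0.49, adjusted p = 0.0224) and 0 fell. A line difference in the regulation of these 3 genes may be the reason, as a hypothesis found on the same data.

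In a fit with 2 groups of 4 libraries, the split by line gave 434 genes and the highest of the other splits gave 0. So 1 of 35 splits reached the real count. In the other splits the line difference stays in the residual, which lowers their counts wherever the lines differ. The splits therefore do not exclude chance. The split by temperature gave 0 genes in that fit, a count that 35 of 35 splits reach by its nature, the highest being the 434 of the split by line, and since the line difference stays in its residual the fit decides nothing. In a fit with the line as a term the temperature split gave 2 genes, against 7 in the model with 4 group means, and the highest of the other splits gave 0. Only the 18 splits that exchange libraries within the lines leave the line difference in place, the real one being the 1 with as many genes, and they are too few for a share under 0.05.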

How the results depend on the processing

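Removal of the length trend and library weights were chosen only after the data were seen; the other alternatives were planned. No paired analysis was possible because the columns of the table carry no replicate number. Where a library was left out, the lone library of its group was assumed to vary like the other groups. Of the 285 results for named genes, no direction turned when a library was left out (1519 kept their call and 761 lost it, counted per gene and library), and under the other alternatives 2460 kept it, 489 lost it and 1 reversed: the CG13646 interaction, -0.09 (adjusted p = 0.914) with a pseudocount of 0.1. Of the 65 results for lists, 346 kept their call, 166 lost it and 6 reversed under the other alternatives, and 441, 76 and 3 with a library left out. Of the named genes that passed, 23 of 50 at 25C, 38 of 85 at 19C and 52 of 84 for the line average held in every alternative, against 0 of 56 for temperature in CantonS, 0 of 2 in Bully and 0 of 4 averaged over lines. Depth limits genes such as CG13646, with 4 reads in 1 library.

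Counts of genes moved as follows, with the cause not tested unless the alternative itself tests fewer genes or libraries. A 2-fold minimum gave 139 (line at 25C), 239 (line at 19C), 77 (CantonS temperature), 150 (line average) and 4 (temperature average). An adjusted p below 0.1 gave 460, 1794, 1703, 1136 and 16 for the same comparisons, and 280 for the interaction. A mean of at least 5 RPKM gave 156 for the line at 25C and 467 for the line average. No filter gave 1 for the interaction, 2 for CantonS temperature, 49 for Bully temperature and 13 for the temperature average. Fits of only the groups compared gave 166 for the line at 25C and 4 for CantonS temperature. Median-of-ratios rescaling gave 0 for CantonS temperature and 3 for the temperature average, and quantile normalization gave 17, 1 (Bully temperature) and 3 (temperature average). Length removal gave 0 for CantonS temperature and 3 for the temperature average, library weights gave 518 (line at 19C), 0 (CantonS temperature), 8 (Bully temperature) and 4 (temperature average), and a pseudocount of 0.1 gave 4 (temperature average). With each library left out the ranges were 77 to 398 (line at 25C), 145 to 1996 (line at 19C), 0 to 903 (interaction), 0 to 2261 (CantonS temperature), 0 to 4 (Bully temperature), 350 to 1171 (line average) and 0 to 312 (temperature average). The highest counts at 19C, in the interaction, in CantonS temperature and in both averages came without CantonS 19C a.

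Counts of lists that passed were 0 in all 7 comparisons with an estimated correlation. Fry gave 0 for the interaction and for all 3 temperature comparisons and 2 for the line average; quantile normalization gave 1 for the line at 25C; and length removal gave 5 for the line at 19C, 7 for the interaction (3 of its 12 and 4 others) and 5 for the temperature average. With each library left out the count was 0 (without Bully 25C a) to 8 for the line at 25C and 8 (without CantonS 19C b) to 15 for the temperature average. Removing the length trend reversed the fast neurotransmitter list (adjusted p = 0.228 in the interaction, 0.406 in CantonS temperature, 0.681 in the temperature average) and the ion channel list (0.515, 0.566 and 0.785). Without CantonS 19C b the fast neurotransmitter list was reversed as well, and its adjusted p ranged over the left-out libraries from 6.28e-06 to 0.813, from 6.65e-07 to 0.709 and from 9.78e-07 to 0.54 in these comparisons.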

Other observations

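Arc1, an activity-regulated gene related to retroviral capsids, was higher in Bully at 25C (1.91, SE 0.31, adjusted p = 0.0145) and at 19C (1.67, SE 0.31, adjusted p = 0.0141), 1 of 11 activity-regulated genes to rise at each temperature, also adjusted over the list alone. In the same list Hsromega fell at 19C (-0.93, SE 0.20, adjusted p = 0.025), also adjusted over the list alone, a call lost without Bully 19C a (0.138), Bully 19C b (0.136) or CantonS 19C a (0.0555) and after quantile normalization (0.0643). At 25C the group mean of Arc1 was 54.5 ± 29.6 RPKM in Bully and 13.1 ± 0.60 RPKM in CantonS (SD, n = 2), and the call was lost without CantonS 25C a or CantonS 25C b (adjusted p up to 0.116). The call at 19C was lost without Bully 19C a, Bully 19C b or CantonS 19C b (up to 0.0972). Of 8 UDP-glycosyltransferase genes 1 rose and 2 fell at 25C (1 and 3 adjusted over the list alone), with Ugt86Dd at -1.64 (SE 0.20, adjusted p = 0.00391), and 2 rose and 2 fell at 19C (3 and 2 adjusted over the list alone), with Ugt86Dd at -1.68 (SE 0.20, adjusted p = 0.00205). Of 28 glutathione transferase genes 2 rose and 1 fell at 25C (6 and 2 adjusted over the list alone) and 0 rose and 4 fell at 19C (4 adjusted over the list alone). Of 26 heat shock protein and chaperone genes Hsp67Bc fell at both temperatures (-1.12, adjusted p = 0.00494 at 25C, and -1.20, adjusted p = 0.00217 at 19C), and 0 rose at either. Averaged over temperatures limma also called Hsp27 higher in Bully (1.07, SE 0.27, adjusted p = 0.0447) and Hsf lower (-0.40, SE 0.10, adjusted p = 0.0391). Of 29 odorant binding protein genes 4 rose and 2 fell at 25C (6 and 4 adjusted over the list alone), and 2 rose and 4 fell at 19C (3 and 5), with Obp57d lower at both (-1.14, adjusted p = 0.0297 at 25C; -2.25, adjusted p = 8.94e-04 at 19C). Obp57d overlaps the cuticle gene Cpr57A, whose values were 1.489 to 1.537 times those of Obp57d in every library, so the reads of these genes cannot be separated. The call of Obp57d at 25C was lost without Bully 25C a, Bully 25C b or CantonS 25C b (up to 0.159).

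Markers of muscle, neurons and glia had 0 calls by limma at 25C among 22, 10 and 11 genes, with 5, 1 and 2 at an unadjusted p below 0.05. At 19C the muscle genes bt (0.66, adjusted p = 0.0354) and Unc-89 (0.55, adjusted p = 0.0363) rose (2 rose and 4 fell adjusted over the list alone), and 0 neuronal genes passed, with 0 at an unadjusted p below 0.05. Both muscle calls were lost without any 1 of the Bully libraries or CantonS 19C b (up to 0.293), and after removal of the length trend (adjusted p up to 0.523). The glial genes moody (0.64, adjusted p = 0.0118), nrv2 (0.86, adjusted p = 0.0143) and CG1732 (0.75, adjusted p = 0.0362) rose and alrm fell (-0.53, adjusted p = 0.0299) at 19C, with 4 and 1 adjusted over the list alone. Each of these calls was lost without Bully 19C a or Bully 19C b (up to 0.25), and that of alrm also after either rescaling (adjusted p up to 0.0974). Camera placed the glial list up at 19C (adjusted p = 0.0248, and adjusted p = 0.47 with an estimated correlation). With each library's length trend removed the list did not pass (adjusted p = 0.144). Genes below 0.1 RPKM in every library of 1 line were counted, and the length trend was removed, only after the values were seen. In 2 genes every Bully library lay below 0.1 RPKM and every CantonS library at 1 RPKM or more: mthl8, at 0.00 to 0.01 RPKM in Bully and 1.51 to 3.86 RPKM in CantonS, and CG3397, at 0.00 to 0.08 RPKM and 1.55 to 3.15 RPKM. The reverse held for 0 genes.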
